A study of Mus musculus with 10 samples.

How the data were processed

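Hypothalamus RNA of male CDF1 mice was hybridised to Affymetrix whole-transcript arrays, 1 array per sample. Tumour-bearing mice had received C26 colon adenocarcinoma cells under the skin in 0.2 ml of buffered salt solution, controls the same volume without cells, and the tissue was taken on day 20, per the labels' protocols. The groups were 3 control mice and 5 tumour-bearing mice on single arrays, and 1 array each of RNA pooled from 4 control and from 5 tumour-bearing mice. The labels do not say whether the pools hold RNA of the same mice, so the pooled arrays entered none of the main tests and were set beside the individual arrays as values; 1 alternative added them as samples.

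The deposited values are log2 expression values that the authors made with RMA, per the submitters' processing notes, with the version and the probe set definition not given in the sources used here. That the scale is log2 was inferred from the range of the values and from RMA. The values are absolute levels, not centred per gene. Array medians were 5.30 to 5.32 in the 8 individual arrays, 5.27 in the control pool and 5.28 in the tumour-bearing pool. Whether all 10 arrays were processed together is not given in the sources used here. RMA sets the arrays to a common distribution, so a shift of all transcripts together cannot be seen, and it compresses folds by an amount that differs between probe sets.

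The table held 35556 probe sets. A platform annotation paired 21218 with exactly 1 gene and 1881 with several, and left 12457 unnamed here. Updating the symbols through their Entrez numbers against the RefSeq annotation of GRCm38.p6 changed 0 of them. That annotation was used for names and for which genes neighbour each other, and no coordinates are given because no build is named for the array. No table marks control probes, so none were removed. Genes were named only from probe sets with 1 gene, and the brightest probe set stood for a gene with several.

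Probe sets above 20 on the linear scale (4.32 on the log2 scale) on at least 3 of the 8 individual arrays were tested, 22837 in all, of which 6905 were unnamed and 1123 had several genes. They covered 12978 genes. A probe set could pass with a whole group below that level; for named genes of this kind the difference is also given with values under the level raised to it, which can understate the change. Tumour-bearing mice were compared with controls by limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend; statmod 1.5.0 for the robust alternative), with Benjamini-Hochberg adjustment over all tested probe sets and a threshold of 0.05. The 32 gene lists, fixed before the data were examined, covered appetite signals, other peptides, leptin and insulin signalling, serotonin, catecholamines, nitric oxide, cytokine, interferon, glucocorticoid, thyroid, fasting, cholesterol, unfolded protein, immediate early, clock, respiratory and ribosomal genes, and markers of cell types and neighbouring tissues. Lists with at least 3 tested genes, 31 in all, were tested with camera at a preset correlation of 0.01, with an estimated correlation and fry as alternatives. A score per animal, the mean centred log2 value of a list, was compared by a two-sided exact permutation test over the 56 splits of 8 animals, whose smallest possible p is 0.0179. The number of arrays limits the precision of every value.

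The text names the called genes with the largest changes (up to 12 each way), a fixed set of feeding and stress genes whatever their result, and from each list up to 4 called members or, where none was called, the member with the largest change. Further list members given as examples were chosen after their values were seen, mostly from those past the adjustment over the list alone. The list of midbrain markers was also written after the values of some members were seen.

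The alternatives were the filter, the variance model, array weights, another normalization, the replicate number as a block, the pooled arrays as samples, the mean of a gene's probe sets, a minimum fold of 1.2, other list tests and leaving out each animal. A further 3 were added after seeing the data: leaving out 2 animals with pituitary transcripts, a midbrain score as a covariate, and testing only probe sets with 1 gene. The gene test was tested on simulated data for the 22837 probe sets with 200 changed: at an absolute log2 change of 0.5 it recovered 53.7% of the changed probe sets, at 1 it recovered 91.0%, and at 2 it recovered 97.0%, with 13 false calls. With nothing changed it made 0 calls. The simulated values were normal and independent, without correlated genes or outlying animals. These rates may therefore be better than those on the real arrays. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.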

Results

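Hypothalamic gene expression was measured in mice carrying the C26 colon adenocarcinoma, a transplantable tumour used as a model of cancer cachexia, and in sham-injected controls. Individual arrays covered 3 control and 5 tumour-bearing mice, and 1 further array per group held pooled RNA. Between individual arrays the correlation over the tested probe sets was 0.980 to 0.989. The comparison addresses how the hypothalamus, which controls food intake, differs in tumour-bearing animals, with attention to appetite genes. Values are log2 RMA levels, with SD over animals or the standard error (SE) of the fitted difference.

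In tumour-bearing mice 10 genes rose and 0 fell past the threshold (limma, 12978 genes tested). The largest change was in Lcn2, which encodes the secreted acute-phase protein lipocalin 2: it went from 4.07 ± 0.28 (SD, n = 3) to 7.12 ± 0.46 (SD, n = 5), 8.28-fold on the deposited scale (log2 difference 3.05 ± 0.25 SE, limma adjusted p = 0.0085). As 2 of the 3 controls lay below the filter level of 4.32, the size of this fold is uncertain: with values under that level raised to it, Lcn2 was at least 6.92-fold higher, still above the fold of the other called genes. Lrg1, another secreted acute-phase glycoprotein gene, rose 3.12-fold (log2 1.64 ± 0.15 SE, limma adjusted p = 0.0085). Serpina3n, a serine protease inhibitor gene induced in reactive astrocytes, rose 1.27-fold, and Mfsd2a, a lipid transporter gene of brain endothelium, rose 1.46-fold. The other 6 were microRNA genes: Mir411 rose by 1.47 on the log2 scale, Mir379 by 1.07, Mir181b-1 by 0.89, Mir369 by 0.67, Mir382 by 0.59 and Mir134 by 0.43, with limma adjusted p from 0.0213 to 0.0498. All 5 tumour-bearing mice lay above all 3 controls for each of the 10 genes. A further 3 probe sets without a gene name here also rose, of which 10429564 had the largest log2 difference, 0.84.

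**Figure D1:**
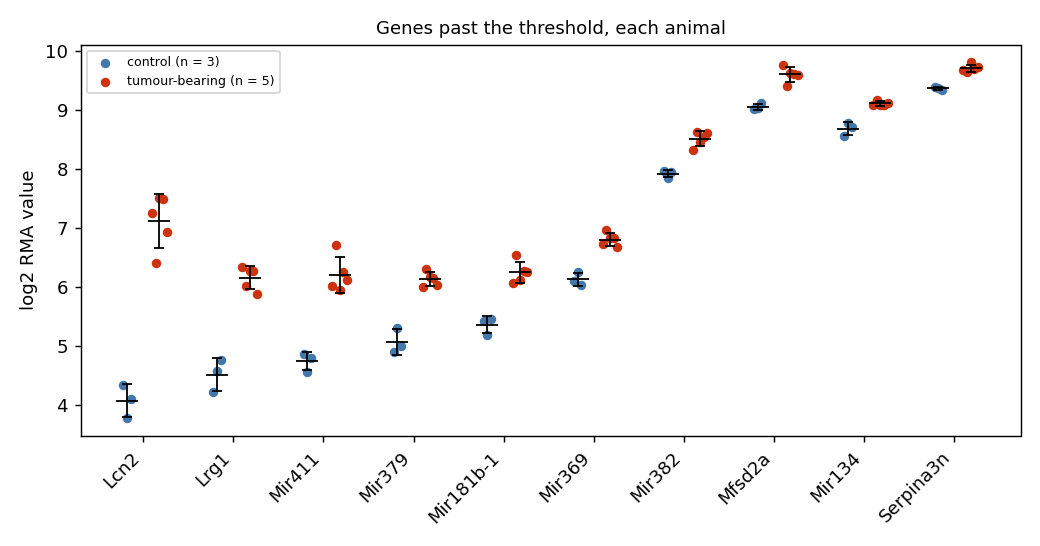
Log2 RMA value (vertical axis) of the 10 genes past the threshold in each control (blue, n = 3) and tumour-bearing mouse (red, n = 5). Points are animals, horizontal marks are group means and bars are 1 SD; the points of the groups do not overlap for any of these genes, and Lcn2 differs most, 4.07 against 7.12.

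No gene was called lower by limma, although at an unadjusted p under 0.05 there were 1335 genes (845 lower and 490 higher) where 648.9 would arise by chance. The absence of lower calls depended on the setting: 29 genes were lower and 24 higher without tumour-bearing mouse 2, and 29 lower and 39 higher when only probe sets with 1 gene were tested, an alternative chosen after seeing the data. The groups did not overlap for 8.30% of genes, against 3.57% by chance. The count of called genes changed with single animals left out, although the differences of the 10 genes stayed at 0.856 to 1.11 times their values. The count was 6, 2 and 0 without control 1, 2 and 3, and 4, 53, 4, 2 and 3 without tumour-bearing mouse 1, 2, 3, 4 and 5. It was 0 without tumour-bearing mice 3 and 4, and 0 with a midbrain marker score as a covariate, both chosen after seeing the data. The midbrain score itself differed between the groups, by -0.56. A call lost with it as a covariate, here or below, therefore does not show where a change comes from.

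Of the fixed set of feeding and stress genes, Lcn2 passed the threshold, and none of its other tested members did. Npy, the appetite-stimulating neuropeptide Y, was 8.58 ± 0.24 (SD, n = 3) in controls and 9.43 ± 0.45 (SD, n = 5) in tumour-bearing mice, 1.80-fold, and higher in 5 of 5 tumour-bearing mice than in any control (log2 0.84 ± 0.23 SE, limma adjusted p = 0.284). Trh, thyrotropin-releasing hormone, differed by 0.49 ± 0.09 SE on the log2 scale (limma adjusted p = 0.135); it passed without tumour-bearing mouse 2 (0.55, limma adjusted p = 0.0282, with 0.0245 to 0.930 over all alternatives). Pomc, the precursor of the satiety peptide alpha-MSH, differed by -0.17 ± 0.09 SE and Cartpt by -0.24 ± 0.14 SE (-0.40 without control 1, -0.14 without control 2 and -0.16 without tumour-bearing mouse 1). The receptor genes differed by 0.22 (Ghsr, the ghrelin receptor), 0.19 (Mc4r), 0.11 (Npy1r), -0.12 (Lepr, the leptin receptor) and -0.08 (Htr2c). Cck differed by -0.18 and Hcrt by 0.02. Several of these small differences moved by over 1.5 times with 1 animal left out. Npy1r was 0.059 without control 2 and 0.063 without tumour-bearing mouse 2, Lepr was -0.062 without control 1, and Cck was -0.12 without control 2 and -0.27 without control 3. Htr2c was -0.13 without control 1, -0.035 without control 3 and -0.048 without tumour-bearing mouse 3. Hcrt ranged from -0.0040 to 0.078 (without tumour-bearing mice 3 and 2) and was below 0 without mouse 3 or 4. Crh and Il1b lay below the filter in both groups, Crh at 3.35 ± 0.12 (SD, n = 3) and 3.89 ± 0.27 (SD, n = 5). Agrp and Pmch had no probe set paired with the gene alone and are not analysed here.

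**Figure D2:**
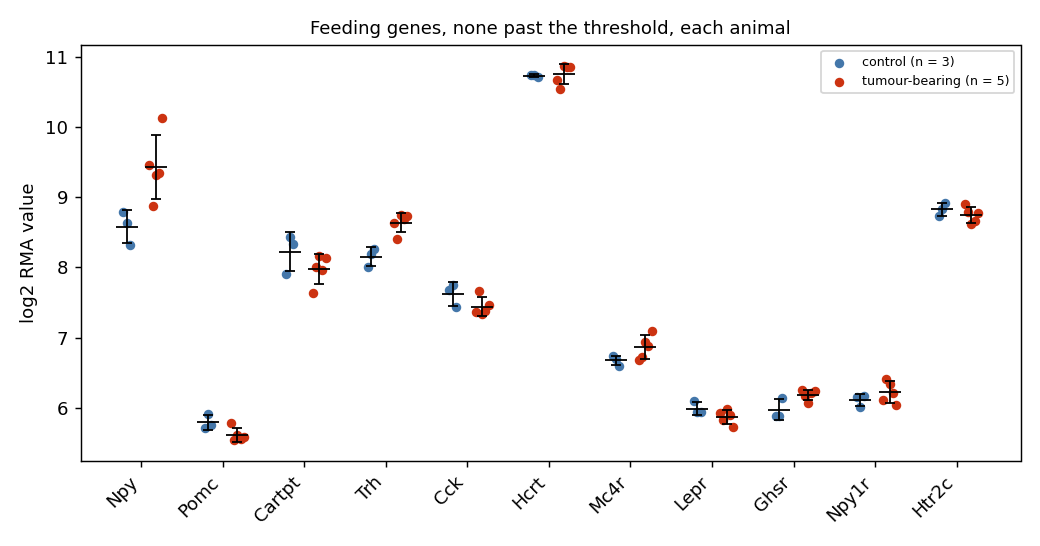
Log2 RMA value (vertical axis) of 11 feeding genes in each control (blue, n = 3) and tumour-bearing mouse (red, n = 5), with group means and 1 SD bars. None passed the threshold; for Npy all tumour-bearing mice lie above all controls, and for Hcrt the group means differ by 0.02.

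The orexigenic list was higher by camera (14 genes, adjusted p = 0.0354, and adjusted p = 0.190 with an estimated correlation), with 9 members higher and 5 lower. Its median difference was 0.08, against 0.84 for Npy, its largest member. The list had 0 members past the adjustment over the list alone (1 without tumour-bearing mouse 2 or 5). The orexigenic call was lost without control 1 (adjusted p = 0.140), without tumour-bearing mouse 3 (0.0760), without both 3 and 4 (0.130), with array weights (0.0698) and with the midbrain covariate (0.584). The anorexigenic list was not called (adjusted p = 0.247), with Trh alone of 26 members past the adjustment over the list alone. The count was 2 without tumour-bearing mouse 2, and 0 without tumour-bearing mice 3 and 4 or with the midbrain covariate. Ucn3 lay below the filter level in all 3 controls and in 2 tumour-bearing mice, and differed by 0.24 with values raised to that level. Of 18 other hypothalamic peptides, 4 rose when adjusted over the list alone and 0 over all genes: Avp, vasopressin, by 0.50 ± 0.07 SE, Oxt, oxytocin, by 0.66 ± 0.18 SE, Vip by 0.46 and Tac2 by 0.29 (camera adjusted p = 0.000136; adjusted p = 0.190 with an estimated correlation). Rln3, relaxin 3, differed by -1.07 ± 0.44 SE, opposite to the list. Among tumour-bearing mice the level of Rln3 was lowest in mouse 3 (3.60) and highest in mouse 2 (5.67). Slc6a3, the dopamine transporter, was lowest and highest in the same mice (6.19 and 9.67). Whether the Rln3 signal came from hypothalamic tissue was not tested. Of the 18 peptides 2 rose without tumour-bearing mouse 3, 2 without tumour-bearing mouse 4, 6 without tumour-bearing mouse 1 and 1 without both 3 and 4, and 1 fell without tumour-bearing mouse 2. The peptide scores of mice 3 and 4, 0.11 and 0.09, were the highest, and these mice also had the highest pituitary marker scores, 0.99 and 0.90. With the midbrain covariate 0 peptides rose, the list median went from 0.08 to 0.02 and the list was not called (adjusted p = 0.419). The median was 0.13 without control 1 and 0.12 without tumour-bearing mouse 1. The thyroid hormone axis (camera adjusted p = 0.0340; adjusted p = 0.190 with an estimated correlation) had 2 of 11 members up, Trh and Hr, and 1 down, the thyroid hormone transporter gene Slco1c1, adjusted over the list alone. Only 1 rose without control 1, control 3, tumour-bearing mouse 4 or tumour-bearing mouse 5, and 0 fell without control 2 or tumour-bearing mouse 4. The thyroid call was lost without control 2 (adjusted p = 0.0561), control 3 (0.201, with the median going from 0.12 to -0.015; it was 0.081 without tumour-bearing mouse 1), tumour-bearing mouse 4 (0.0554) or both 3 and 4 (0.0771, with 1 up and 0 down), and with the midbrain covariate (0.305, with 0 up and 0 down). Leptin and insulin signalling was not called (adjusted p = 0.0911) but was called higher without control 1 (adjusted p = 0.0310). Socs3, a feedback inhibitor of cytokine and leptin receptors, differed by 0.44 ± 0.16 SE, or 0.27 with the values of 2 controls and 1 tumour-bearing mouse raised to the filter level.

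Cytokine and NF-kB response genes were higher. Of 21 tested members 3 rose over all genes (Lcn2, Lrg1 and Serpina3n) and 6 adjusted over the list alone, adding the interleukin 1 receptor Il1r1 (log2 1.01 ± 0.14 SE), the oncostatin M receptor Osmr (0.66 ± 0.10 SE) and Il6ra (0.21 ± 0.07 SE). The list passed camera (adjusted p = 2.77e-10) and, alone of the 31, with an estimated correlation (adjusted p = 0.0266). Its score differed by 0.41, with all tumour-bearing mice above all controls (exact permutation p = 0.0179, the smallest possible; adjusted p = 0.111). The median difference of its members was only 0.15, as a few genes such as Lcn2, Lrg1 and Il1r1 raise the mean. Of the 21 tested among 33 listed members, 17 were higher and 4 lower. The interferon list was lower by camera (adjusted p = 0.0269; adjusted p = 0.404 with an estimated correlation), with 0 of 16 members past the adjustment over the list alone; Rsad2 differed by 0.53 ± 0.42 SE, and by 0.17 without tumour-bearing mouse 3, whose level was 6.95. The interferon call was lost without control 1 (adjusted p = 0.402) and without tumour-bearing mouse 1 (0.104).

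Glucocorticoid target genes were higher: 23 of 25 had a positive difference, 12 rose adjusted over the list alone and 1, Lcn2, over all genes. Lcn2, Il6ra, Nfkbia and Cebpb are also on the cytokine list, so the results of these lists are not independent. Among the 12 were Plin4, a lipid droplet protein gene (log2 1.18 ± 0.24 SE), the cell cycle inhibitor Cdkn1a (0.60 ± 0.16 SE), Tsc22d3, also called GILZ (0.36 ± 0.06 SE), and the metallothionein Mt1 (0.20 ± 0.04 SE). Fkbp5 differed by 0.32 ± 0.15 SE and was not among them (0.21 without tumour-bearing mouse 1). The camera adjusted p was 4.76e-17, and adjusted p = 0.182 with an estimated correlation. With the midbrain covariate 5 members rose, while the list median was 0.29 in place of 0.24 and the camera adjusted p was 4.97e-17.

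Cholesterol synthesis genes were lower, with all 17 tested members below 0, 12 of them past the adjustment over the list alone and 0 over all genes. Idi1 fell by 0.44 ± 0.09 SE on the log2 scale, Hmgcs1, which makes the precursor of mevalonate, by 0.31 ± 0.06 SE, and Sqle, squalene epoxidase, by 0.29 ± 0.05 SE. The camera adjusted p was 4.93e-14, and adjusted p = 0.182 with an estimated correlation. Oligodendrocyte markers, genes of the myelin-forming glia, were also lower in all 12 tested members, 9 of them past the adjustment over the list alone and 0 over all genes. Opalin fell by 0.95 ± 0.25 SE, Ugt8a by 0.81 ± 0.19 SE and Mag by 0.57 ± 0.18 SE (camera adjusted p = 2.87e-10; adjusted p = 0.201 with an estimated correlation). Without control 2 the counts were 7 and 5, and without control 3 they were 6 and 5, for cholesterol and oligodendrocyte genes. Without tumour-bearing mice 3 and 4 they were 11 and 4. With the midbrain covariate both counts were 0, but the lists differed: the cholesterol median went from -0.25 to -0.18 and the list remained called by camera (adjusted p = 7.90e-06), while the oligodendrocyte median went from -0.50 to -0.13 and its call was lost (adjusted p = 0.201).

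**Figure D3:**
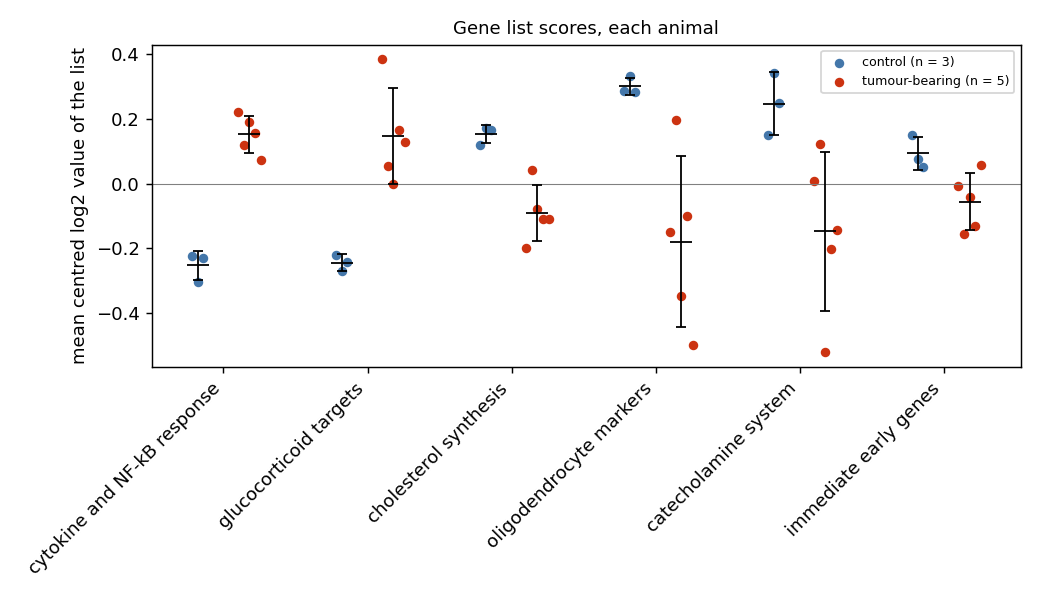
Mean centred log2 value (vertical axis) of 6 gene lists in each control (blue, n = 3) and tumour-bearing mouse (red, n = 5), with group means and 1 SD bars. The groups do not overlap for the cytokine, glucocorticoid, cholesterol, oligodendrocyte and catecholamine scores, although 1 tumour-bearing mouse lies close to the controls for oligodendrocyte markers. For immediate early genes tumour-bearing mouse 5 (0.058) lies above control 3 (0.052).

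Catecholamine genes were lower: of 10 tested members 3 fell adjusted over the list alone and 0 over all genes, Th, tyrosine hydroxylase, by 0.93 ± 0.20 SE, the vesicular transporter Slc18a2 by 0.72 ± 0.16 SE and Ddc by 0.44 ± 0.13 SE (camera adjusted p = 0.00209; adjusted p = 0.262 with an estimated correlation). Slc6a3, the dopamine transporter, differed by -1.58 ± 0.60 SE and its level was 6.19 in tumour-bearing mouse 3 and 9.67 in mouse 2. The serotonin list was not called (adjusted p = 0.220); Slc6a4, the serotonin transporter, differed by -1.31 ± 0.51 SE, by -2.12 without control 1, when it passed (limma adjusted p = 0.0430, with 0.0430 to 0.948 over all alternatives), and by -0.78 without control 2. Slc6a4 lay below the filter level in 1 control and 3 tumour-bearing mice, and differed by -1.24 with values raised to that level. Its level was 3.78 in control 1, as low as in tumour-bearing mice, against 6.45 and 5.93 in the other controls. Tph2, which makes serotonin, did not pass the filter and was split in the same way, at 3.19, 5.99 and 5.13 in controls 1, 2 and 3 against 3.35 ± 0.28 (SD, n = 5) in tumour-bearing mice. Because control 1 lay with the tumour-bearing mice for Slc6a4 and Tph2, these values do not separate the tumour from the tissue dissected. The score of midbrain markers, several of which are themselves genes of dopamine neurons, differed by -0.56 (exact permutation p = 0.0714). In the pooled arrays the catecholamine list's mean difference was 0.09, against -0.40 in the individual arrays. With the midbrain covariate 0 catecholamine members fell, the median went from -0.21 to -0.04 and the list was not called (adjusted p = 0.874). The median was -0.32 without control 1 and -0.13 without control 2. Of the catecholamine members 5 fell without tumour-bearing mouse 2, and 2 without control 1, control 2, tumour-bearing mouse 4 or tumour-bearing mouse 5.

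Immediate early genes, which follow neuronal activity, were lower: 4 of 18 fell adjusted over the list alone and 0 over all genes, Fos by 0.52 ± 0.16 SE, Nr4a2 by 0.44 ± 0.07 SE, Egr1 by 0.40 ± 0.12 SE and Nr4a3 by 0.38 ± 0.09 SE (camera adjusted p = 0.00301; adjusted p = 0.262 with an estimated correlation). Only 1 fell without control 1, tumour-bearing mouse 2 or tumour-bearing mouse 4, and 2 without control 2. In the pooled arrays 9 of 18 were higher and 9 lower. The circadian list was higher by camera (adjusted p = 0.00209; adjusted p = 0.212 with an estimated correlation), with Per2 differing by 0.30 (0.15 without control 1); in the pools 9 members were higher and 8 lower. Ribosomal protein genes were higher by camera (adjusted p = 0.000178; adjusted p = 0.190 with an estimated correlation) by a median of only 0.05, with 1 of 20 members, Rps18, past the adjustment over the list alone (0 without any 1 of the controls or without tumour-bearing mouse 2, 3 or 4) and Rpl14 differing by -0.20 (-0.13 without control 2 and -0.32 without control 3). The ribosomal call was lost with the midbrain covariate (adjusted p = 0.184), and in the pools 8 members were higher and 12 lower, with a median of -0.05. Oxidative phosphorylation genes were lower by camera (adjusted p = 0.00350; adjusted p = 0.262 with an estimated correlation) by a median of -0.06 (-0.088 without control 1 and -0.031 without control 2), with Sdhb differing by -0.16. This call was lost without control 2 (adjusted p = 0.0877) and with the midbrain covariate (0.515). Fatty acid and fasting genes (adjusted p = 0.645), nitric oxide genes (adjusted p = 0.645; Ddah2 differed by -0.13, and by -0.026 without control 3) and unfolded protein response genes (adjusted p = 0.220; Dnajb9 differed by 0.13) were not called. For the fatty acid list the median was -0.04 (-0.013 without tumour-bearing mouse 1, -0.056 without mouse 4 and -0.016 without mouse 5) and the mean 0.11, so they differ in sign.

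Markers of other cells and neighbouring tissue also varied. Microglia markers were lower by camera (adjusted p = 0.0444; adjusted p = 0.454 with an estimated correlation), with Cd53 differing by -0.34, as were meningeal markers (adjusted p = 0.00467; adjusted p = 0.443 with an estimated correlation), with Mgp differing by 0.51. The microglia call was lost without control 1 (adjusted p = 0.330), control 3 (0.0824), tumour-bearing mouse 1 (0.128) or 5 (0.125) and with the midbrain covariate (0.515), and the meningeal call without control 3 (0.164). Striatum markers (adjusted p = 0.000931; adjusted p = 0.305 with an estimated correlation) and cortex and hippocampus markers (adjusted p = 0.00556; adjusted p = 0.262 with an estimated correlation) were higher. Of 9 striatum markers 2 rose adjusted over the list alone, Gpr6 and Rgs9 (0 without any 1 of the controls or without tumour-bearing mouse 3, 4 or 5). Of 9 cortex and hippocampus markers 2 rose likewise, Tbr1 and Nrgn (1 without control 2, control 3 or tumour-bearing mouse 1, 3 or 5). Tbr1 lay below the filter level in all 3 controls and differed by at least 0.61 with values raised to that level. The cortex and hippocampus call was lost without control 2 (adjusted p = 0.101). Erythroid markers (adjusted p = 0.0291; adjusted p = 0.305 with an estimated correlation) and pituitary markers (adjusted p = 0.0291; adjusted p = 0.190 with an estimated correlation) were higher as well. Among erythroid markers Alas2 rose by 1.41 ± 0.42 SE adjusted over the list alone, with 0 members up without control 2, control 3 or tumour-bearing mouse 4 and 2 without mouse 3. The erythroid call was lost without control 2 (adjusted p = 0.0662) or control 3 (0.0796). The pituitary call was lost without control 1 (0.0544), control 3 (0.0606), tumour-bearing mouse 3 (0.0793) or both 3 and 4 (0.0624). With the midbrain covariate neither was called (adjusted p = 0.874 and 0.939). Gh, growth hormone of the pituitary, was 10.5 in tumour-bearing mice 3 and 4 and 9.82 in the tumour-bearing pool, against 4.21 to 4.45 in controls. Neuron (adjusted p = 0.247, Nefm -0.43), astrocyte (adjusted p = 0.726, Aqp4 -0.51), endothelial (adjusted p = 0.645, Vwf 0.82), tanycyte and ependymal (adjusted p = 0.220, Enkur 0.27), choroid plexus (adjusted p = 0.726, Otx2 -0.44) and thalamus markers (adjusted p = 0.657, Rgs16 0.23) were not called, the value beside each being the log2 difference of its largest member. Aqp4 passed without tumour-bearing mouse 2 (-0.60, limma adjusted p = 0.0222, with 0.0222 to 0.934 over all alternatives). Without control 1 neuron markers were called lower (adjusted p = 0.00467) and tanycyte and ependymal markers higher (adjusted p = 0.0188), and with array weights neuron markers were called lower (adjusted p = 0.0412). Camera put the astrocyte and endothelial lists on the higher side, although the medians were -0.0030 and -0.019 and the means -0.027 and 0.019. With 1 animal left out the astrocyte median ranged from -0.014 to 0.029 (without tumour-bearing mice 2 and 5). The endothelial median ranged from -0.094 to 0.080 (without controls 1 and 3). Some of the single-gene values moved by over 1.5 times with 1 animal left out. Nefm was -0.75, -0.26 and -0.28 without control 1, 2 and 3, Enkur was 0.48 and 0.15 without control 1 and 2, Rgs16 was 0.077 without control 1, and Otx2 was -0.29 without tumour-bearing mouse 5. Of 14 leukocyte markers only 2 could be tested, Ptprc with -0.09 (-0.054 without control 1, -0.17 without tumour-bearing mouse 2 and -0.060 without tumour-bearing mouse 5).

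By camera 19 of 31 lists were called, 11 higher and 8 lower, but only 1 with an estimated correlation. At the preset correlation camera also called at least 1 list in nearly all wrong splits of the animals, and up to 18. Some of those splits hold part of the group difference. The adjusted p values of camera at that setting can thus overstate the evidence for single lists. The score test per animal called 0, where 1 call would need 12 lists at its smallest possible p. Of the lists, 9 had an unadjusted exact permutation p under 0.05, and fry called 2. The cytokine, glucocorticoid, cholesterol, ribosomal and serotonin lists reached the smallest possible exact permutation p, 0.0179. For 2 of these lists the groups were barely apart. The nearest serotonin scores were -0.021 (control 1) and -0.025 (tumour-bearing mouse 2). The nearest ribosomal scores were 0.0030 (control 1) and 0.0049 (tumour-bearing mouse 1). Of the serotonin members 6 were higher and 9 lower, and Slc18a2 and Ddc are also on the catecholamine list. Oligodendrocyte markers (exact permutation p = 0.0536) and immediate early genes (0.0714) missed 0.05.

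The pooled arrays were a second measurement of the same contrast without replicates. They correlated at 0.990 with each other and at most at 0.986 with any individual array. Levels of some genes in the pools lay apart from those in single mice. Pomc was 6.67 in the control pool and 6.59 in the tumour-bearing pool, against 5.55 to 5.91 in individual mice. Serpina3n was 9.79 in the control pool, against 9.33 to 9.39 in control mice. Across the tested genes, which are not independent replicates, the pool difference and the individual difference correlated with r = 0.486 and rho = 0.327. All 10 called genes had the same sign in the pools, from 0.23 for Mir379 to 2.66 for Lcn2. Lrg1 was larger there (2.30 against 1.64), while Mir379 (0.23 against 1.07) and Mir181b-1 (0.46 against 0.89) were smaller. Of the 1335 genes at an unadjusted p under 0.05, 80.1% had the same sign, against 60.9% of all tested genes. All 17 cholesterol genes were lower, 11 of 12 oligodendrocyte markers were lower and 23 of 25 glucocorticoid targets were higher in the pool of tumour-bearing mice. Of the 19 lists called by camera, 16 had a pool median in the direction of the call, and 3 had the opposite sign, namely catecholamine (0.026), immediate early (0.021) and ribosomal protein genes (-0.05). The pools may hold RNA of the same mice, so this is not shown to be an independent repeat.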

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

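Among 50 named genes and 31 list scores, 6 had 1 tumour-bearing mouse far from the other 4, where chance alone would give 4.05. For Ppp1r1b, a striatal gene, the gap of mouse 1 to the nearest other was 0.870 of the group's range (7.47 against 5.62 to 5.86), and for the striatum score, mouse 1 again, 0.786. For the erythroid score mouse 3 stood apart with a ratio of 0.754. The ratio was 0.766 for Otx2 (mouse 5, 4.26), 0.713 for Pomc (mouse 1, 5.79) and 0.716 for Ptprc (mouse 2, 4.98). No explanation was tested for these.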

How the results depend on the processing

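The settings that leave out mice 3 and 4, use the midbrain covariate or test only probe sets with 1 gene were chosen after seeing the data. The main count was 10 genes, 10 higher and 0 lower. It was 3 (3 higher) with no filter and 3 (3 higher) without the intensity trend, 18 (17 higher, 1 lower) with a stricter filter, and 17 (15 higher, 2 lower) with array weights. With the pooled arrays added, without a term for their different levels, 1 gene was lower. Leaving out each animal gave 0 to 53 genes, 0 to 24 higher and 0 to 29 lower. Without mice 3 and 4 it was 0 (0 higher), and with the midbrain covariate 0 (0 higher). With that covariate Lcn2 differed by 2.30 in place of 3.05. The loss comes with fewer samples, or with 1 fewer residual degree of freedom and a covariate that itself differed between the groups, by -0.56. Such a covariate takes up part of the group difference, so a call lost with it does not show where a change comes from. Testing only probe sets with 1 gene gave 68 (39 higher, 29 lower), including the same 10. Adjusting over these probe sets with the variance prior of all gave 10, so the rise comes from the prior, whose degrees of freedom went from 3.44 to 6.67; the median residual SD was 0.0988 for these probe sets and 0.200 for the others. The main count was kept as designed. For the remaining changes the cause was not tested.

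With the replicate block the count was 0 (0 higher), and the lists called were 17. In that fit tumour-bearing mice 4 and 5 shared no block with a control and added nothing to the contrast. The lost gene calls thus come with fewer samples. Same-numbered animals did not deviate together (correlations -0.0020, 0.0084 and 0.0089), so the numbers do not pair the samples. Of 19 lists, 1 was called with an estimated correlation, 2 with fry and 9 with the midbrain covariate; camera has no robust setting, so that alternative was not run for lists. The score test called 0 lists in each setting run, which says nothing about stability: 1 adjusted p under 0.05 would need 12 of 31 lists at the smallest possible p, 30 without 1 control and 18 without 1 tumour-bearing mouse, and cannot be had without mice 3 and 4. The call by camera was lost with array weights for the orexigenic (adjusted p = 0.0698), interferon (0.182), microglia (0.355) and meningeal lists (0.0747), while neuron markers became called as lower (0.0412). It was lost with a stricter filter for the interferon, microglia and pituitary lists (each 0.0658), with the replicate block for the interferon (0.0963) and microglia lists (0.104), and with the pooled arrays added for the microglia list (0.114); the erythroid list could not be tested with the stricter filter. The correlation with the pools, 0.486, was 0.351 with no filter, 0.543 with a stricter filter, 0.444 without mice 3 and 4, and 0.425 to 0.495 leaving out each animal. Of 1038 values of named genes under an alternative, 931 kept their side of the threshold, 100 lost the call, 7 gained it and 0 changed sign with a call in either setting. Lcn2 kept its call in 17 of 21 alternatives, Lrg1 in 16 and Mir181b-1 in 8.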

Other observations

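Except for the counts over other splits of the animals, the tests here were chosen after the results were seen. Of the 56 splits of the 8 animals into 3 and 5, only 1, the real one, called as many as 10 genes. The highest other called 0. A chance division of the animals is thus unlikely for this count, though 1 of 56 is the smallest share possible here. For gene lists 1 of 56 splits, the real one, reached 19. The margin was small, so this count argues only weakly against a chance division and bears on no single list. The highest other reached 18, with tumour-bearing mice 1, 3 and 4 set against all the rest, a split that keeps the controls together and so holds part of the group difference in reverse; splits that divided the controls reached at most 15.

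MicroRNA genes were higher as a class. Of 34 tested microRNA genes between Meg3 and Dio3 in the annotation's order, 33 had a positive difference, with a median of 0.27 (score difference 0.34, exact permutation p = 0.0179), and 5 were called. Outside it 75 of 96 were positive, with a median of 0.16 (exact permutation p = 0.0179, the smallest possible). Meg3 and Rian together differed by -0.0032 ± 0.0269 SE, which argues against a rise of these long transcripts of the region. Mirg, a further transcript there, was not tested, so a higher host transcript of the called microRNA genes is not excluded. A shift of all dim probe sets is argued against, since 0% of 10000 random lists matched on level had a median as high, the highest being 0.0689. A shift of small RNA in the preparations may remain: small nucleolar RNA genes differed by 0.08 (exact permutation p = 0.393), which does not settle it. Whether these probe sets detect precursor, mature or other RNA was not tested, nor was processing of the precursors.

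Monoamine genes (Th, Slc6a3, Slc18a2 and Ddc) were lower by -0.92 ± 0.33 SE on average. Less midbrain in the dissected pieces is a candidate explanation: the score of 10 midbrain markers differed by -0.56, but with exact permutation p = 0.0714, and values of 7 of these markers had been seen when the list was written. The 3 not seen gave -0.46 (exact permutation p = 0.0357), mostly from Slc10a4. With the score as a covariate the monoamine difference was 0.02 ± 0.11 SE, 0.207 standard errors from 0, so no fall beyond that of the markers was seen. This cannot decide the origin, because the score itself differed between the groups and most of its markers had been seen. Since several markers are themselves genes of dopamine neurons, less midbrain tissue and a joint fall in those neurons with the tumour cannot be told apart.

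Cholesterol synthesis and oligodendrocyte genes were lower together. Fewer oligodendrocytes in the pieces may account for the cholesterol genes: with the oligodendrocyte score as a covariate the cholesterol difference went from -0.24 ± 0.05 SE to -0.16 ± 0.08 SE, -2.04 standard errors from 0, short of the bound of -2.57 for 95% on so few animals, so this stays open, although it just passed the bound of 2 first written down, after the scores had been seen. The falls of the oligodendrocyte markers differed among themselves, from -0.95 to -0.02 (Cochran's Q = 40.8 on 11 degrees of freedom, above the 95% point of 19.7), but arrays compress folds unequally between probe sets, so a lower share of these cells alone is not excluded. An effect of the tumour on myelin or sterol genes was not tested apart from composition.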
